A study of Homo sapiens with 40 samples.

How the data were processed

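The labels describe H1 and H9 human embryonic stem cells on Matrigel in mTeSR medium, transduced with lentivirus in the presence of polybrene and sampled on days 0 to 7. RNA was extracted with Trizol and treated with DNase, and biotinylated cRNA was made with the Illumina TotalPrep kit, per the labels' protocols, for 1-colour Illumina bead arrays. The values used are probe intensities on a linear scale, deposited by the authors as their processed table. The software, its version and the normalization are not given in the sources used here. From the values, the intensity columns were quantile normalized by the authors: at least 98.4% of the sorted values of each deposited column were found exactly in the first column. They were not background subtracted, since the lowest deposited intensity was 91.0 and the medians lay between 135.619 and 135.686.

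A further deposited table holds signals and detection p-values under column names that match no label, so its 80 value columns were not used, and only its probe order was read. The planned background correction and detection filter needed those columns. In their place, the intensities were corrected by normexp with an offset of 50 and taken to log2, with no further normalization. A probe passed when its intensity was above 145 on at least 4 arrays. That level is the 99th percentile, from the median and a robust SD, of 457 probes for olfactory receptors, which stand in for unexpressed genes. It left 24706 probes. On the log2 scale the level is 6.58, and "above background" means above it. A fold written as "at least" sets the mean of the brighter group against the mean, per dim array, of the higher of this level and the probe's own value, since a dim probe has only a bound. A list median at bounds sets such members at their bound, or at 0 where none can be given. Counts of genes at least 2-fold apart rest on fitted differences and are not bounds. The filter and the offset were set after the files were seen.

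In the H9 columns the values stood 2 rows too early from a break onward, in the probe order of the further table. Over all rows as deposited, mean H9 and H1 levels correlated at 0.443, at 0.987 before the break and 0.224 after it, and at 0.990 after it once moved by 2 rows. The H9 values were moved accordingly, and 30 probes around the break were left out. Every H9 value after the break rests on this repair. The NANOG shRNA column of day 7 had a median of 6.80 and a highest value of 3171, on an unknown scale, and was left out of all comparisons.

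Probes were named through the platform annotation, with symbols updated through the gene identifiers of the current gene table. 30113 probes had 1 gene symbol, 8 had several and 17202 had no gene listed. Of the single symbols 30074 were found in the current gene table and 39 keep the deposited annotation. A gene was represented by the passing probe with the highest mean level, and 3716 of the 13438 genes tested had several. Another 144 probes of sex-linked marker genes were left out. Coordinates are not given, because no file names a genome build.

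Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on cell means of arm by window of days (days 0 and 1, days 2 and 3, days 4 to 7), with all 39 arrays sharing 1 estimate of the spread. A Benjamini-Hochberg adjusted p under 0.05 is a call, and every adjusted p for a gene is from limma, except those of the exact permutation tests of the targeted genes. Of 13 contrasts, the late differences from control and the changes over time are the main ones. Fixed in advance were 16 gene lists, tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 16 lists of a contrast. They were pluripotency, trophoblast, endoderm, primitive streak, mesoderm, neuroectoderm, neural crest, BMP response, NODAL and activin response, epithelial to mesenchymal, proliferation, p53 response, interferon, hypoxia and glycolysis, fibroblast feeder, and blood and endothelial, the last few for cell types a culture could hold. The arms, windows, tests, lists, most alternatives and the rule for named genes were chosen before the data were examined. That rule takes the targeted genes, the 5 largest rises and falls among calls with the same sign on every late day, and up to 3 members per list, or the 3 largest each way for pairwise and time contrasts. Other genes were named after their values were seen: those behind counts of 5 or fewer, list members that went against their list, the remaining interferon calls, the genes shared by all knockdowns, and DNMT3B, UTF1, OTX2, L1TD1, MESP1, WNT3A, IFIT3, IFI27, IFI44 and CDKN1A.

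Sample numbers mark the day per the labels, so arrays of 1 day pair across arms. Deviations from the window means had 56 distinct same-day correlations, of which 33 (58.9%) were above 0.1, with a median of 0.128 and a range from -0.14 to 0.45. The fit with the day as a block was run as an alternative. Median differences over all genes lay between -0.011 and 0.010 in every contrast. The quantile normalization holds these medians close together, so they cannot show whether levels shifted as a whole. No pair of arrays was identical, the highest correlation of 2 arrays being 0.992.

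The test script was checked on simulated data for 13438 genes, 50 of them changed at each of 4 sizes. Every array was drawn as independent noise of the fitted spread about the late control mean, with the same change on each late day. The simulated arrays lack the same-day correlation and the trends over days of the real ones, so the recovery there may differ. For OCT4 shRNA it recovered 50, 47, 34 and 2 of 50 genes at log2 changes of 2, 1, 0.5 and 0.25, with 9 false calls. For NANOG shRNA it recovered 50, 49, 27 and 3, and for SOX2 shRNA 50, 49, 28 and 1, with 5 and 8 false calls. Alternatives covered the background correction, the normalization, the filter, single probes, the day block, the arrays in the fit, the variance model, array weights, the windows, the contrasts and each left-out day or array. An offset of 16, days 4 to 6 alone, H9 genes in rows not moved, centring of each array, the list tests on days 0 and 1, the exact test over same-day pairs and the H9 and H1 difference with values at the background level were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.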

Results

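Gene expression was measured in human embryonic stem cells after lentiviral delivery of a short hairpin RNA (shRNA) against NANOG, OCT4 or SOX2, which are transcription factors of the pluripotent state. H1 and H9 are established human embryonic stem cell lines. Each of 5 arms held 8 arrays, 1 per day from day 0 to day 7: H1 cells with control virus, H1 cells with NANOG, OCT4 or SOX2 shRNA, and H9 cells with OCT4 shRNA. The H9 line had no control arm. Of 40 arrays, 39 entered the comparisons, and 1 (NANOG shRNA, day 7) was left out for its unlike scale. The deposited columns were already quantile normalized, which sets their nearly equal medians (135.619 to 135.686 intensity units) and shares of probes above background (40.9% to 41.0%). The number of arrays limits the precision. Days 4 to 7 of an arm stood in for replicates (n = 4, or n = 3 with NANOG shRNA), and levels are normalized log2 intensities, given as mean ± SD. Each arm is 1 time course, so p-values measure the scatter of days about a window mean and not the spread between independent cultures.

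The targeted genes were examined first, as a check of the labels. POU5F1, the gene of OCT4, was at 6.79 ± 0.29 (SD, n = 4) in H1 cells with OCT4 shRNA and at 12.70 ± 0.13 (SD, n = 4) in control cells, a log2 difference of -5.91. NANOG was at 6.66 ± 0.22 (SD, n = 3) with NANOG shRNA against 8.77 ± 0.25 (SD, n = 4), a difference of -2.11, and 2 of its 3 late arrays were above background. SOX2 was at 10.16 ± 0.18 with SOX2 shRNA against 12.16 ± 0.25 (SD, n = 4 each), a difference of -1.99. NANOG and POU5F1 ended close to the background level of 6.58, which limits how far their values could fall, and SOX2 did not. The sizes of these differences therefore do not rank the knockdowns. Each targeted gene was lower on every late array than on every control array (exact permutation test, two-sided, p = 0.0286, the smallest the design allows; 0.0429 after Benjamini-Hochberg adjustment over 9 tests). That test shuffles arrays freely. An exact sign-flip permutation test over same-day pairs cannot pass with so few days, and gave its smallest two-sided p for each targeted gene, 0.125 with 4 pairs and 0.25 with the 3 of NANOG shRNA. The knockdowns also differed in the genes they did not target. OCT4 shRNA lowered NANOG by a log2 of -2.22 (above background on 1 of 4 late arrays) and SOX2 by -3.55, and NANOG shRNA lowered POU5F1 by -1.18 (exact permutation p = 0.0286 for each). With SOX2 shRNA, NANOG differed by 0.00 (exact permutation p = 0.971) and POU5F1 by -0.06 (exact permutation p = 0.629). SOX2 differed by 0.09 with NANOG shRNA (exact permutation p = 0.714).

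The arms reached these levels on different days. In the OCT4 shRNA arm POU5F1 was at 12.33 on day 0, 10.97 on day 1, 8.69 on day 3 and 6.46 on day 7. NANOG and SOX2 were already low in their own arms at the start, at 7.80 against 8.91 in control cells for NANOG on day 0 and at 9.98 against 11.76 for SOX2. A further probe of SOX2 gave -3.04 in the SOX2 shRNA arm and a further probe of NANOG gave -1.88 in the NANOG shRNA arm. A second POU5F1 probe lay near background in every arm, between 6.21 and 7.28, and differed by only -0.30 with OCT4 shRNA and -0.34 with NANOG shRNA. Probes of POU5F1 can share signal with its processed pseudogenes, so its lowest levels are uncertain.

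**Figure D1:**
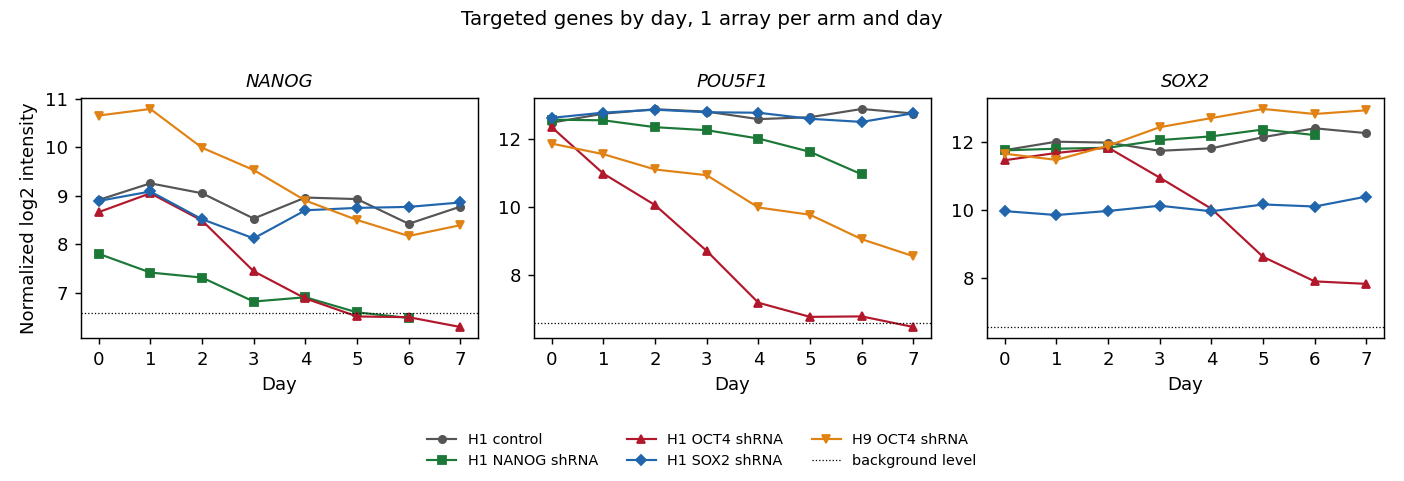
Normalized log2 intensity of NANOG, POU5F1 and SOX2 (y axis) by day (x axis), 1 array per point, with 1 line per arm and the background level dotted. POU5F1 went from 12.33 to 6.46 in H1 cells with OCT4 shRNA and from 11.85 to 8.54 in H9 cells with OCT4 shRNA.

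Few early differences between the arms were called, with 2 arrays per arm. On days 0 and 1, limma called 1 gene with NANOG shRNA, which was NANOG itself (log2 -1.47, adjusted p = 0.0448). With OCT4 shRNA it called 2 genes, RNF157 (log2 0.71) and the small nuclear RNA gene RNU6ATAC (log2 1.22), and with SOX2 shRNA 0. At an unadjusted limma p under 0.05 the numbers were 487, 699 and 532 of 13438 genes. None is far above the share of 0.05 that unchanged genes would give, so these numbers alone are no sign of further early differences. With 2 arrays per arm they cannot show that such differences are absent. Of the 2-fold late calls with SOX2 shRNA, 91.9% had the same sign on days 0 and 1. SOX2 was lower by a log2 of -1.97 in its own arm in this window and did not pass (adjusted p = 0.107). Without day 0, 1, 5, 6 or 7 of all arms the NANOG shRNA count was 0, without day 0 or 1 the OCT4 shRNA count was 0 and without any of days 2 to 6 it was 1, and the SOX2 shRNA count was 1 without day 4 and 2 without day 7. On the day 0 arrays alone, at least 2-fold differences from control numbered 2 with NANOG shRNA, 1 with OCT4 shRNA and 2 with SOX2 shRNA. On the day 1 arrays they numbered 19 higher and 25 lower with NANOG shRNA, 15 and 8 with OCT4 shRNA, and 9 and 14 with SOX2 shRNA. On the day 6 arrays they numbered 250 higher and 246 lower with NANOG shRNA, 751 and 829 with OCT4 shRNA, and 67 and 90 with SOX2 shRNA. These daily numbers set single arrays side by side and have no replicate check.

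**Figure D2:**
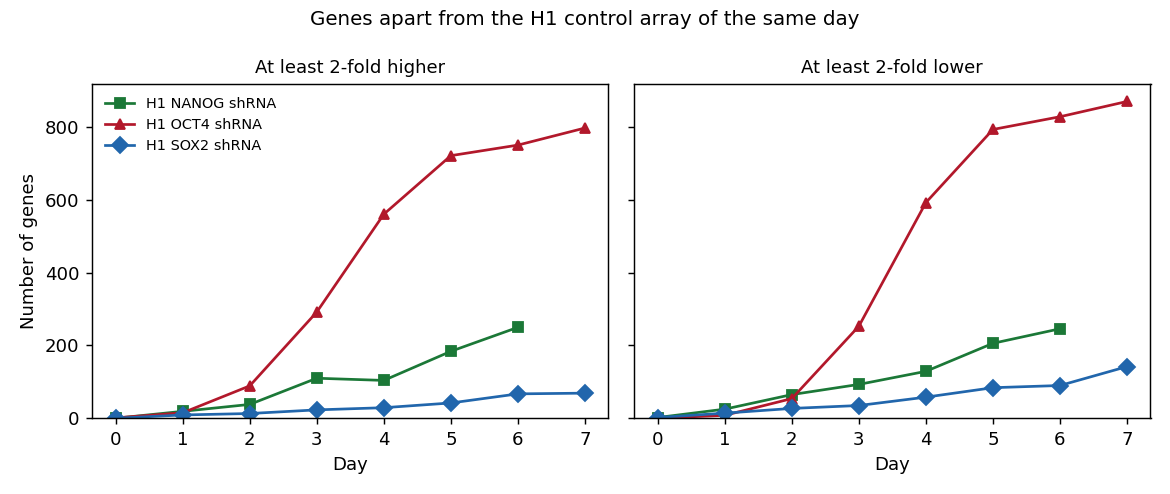
Number of genes (y axis) at least 2-fold higher or lower than the H1 control array of the same day (x axis, days 0 to 7), 1 line per H1 knockdown arm. On day 7 the OCT4 shRNA line stood at 798 higher and 871 lower and the SOX2 shRNA line at 69 and 142.

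The comparison of OCT4 shRNA with control asked which transcripts differ in H1 cells on days 4 to 7. Genes of trophoblast and extraembryonic ectoderm were higher: 19 of 24 measured members rose and 0 fell, with a median log2 difference of 1.54 (1.497 with members below background in a group at their bound). HAND1, a transcription factor of trophoblast and cardiac mesoderm, stood at 13.91 ± 0.23 (SD, n = 4) against a control below background on all 4 arrays, at least 162-fold higher. GABRP, a GABA receptor subunit, was higher by a log2 of 5.70 ± 0.28 (SE) and the LIM homeobox gene ISL1 by 5.59 ± 0.35 (SE), with ISL1 above background on 1 of 4 control arrays. Mesoderm and mesenchyme genes rose in 18 of 22 cases and fell in 2 (THY1 and KDR), with a median of 2.10 (1.79 at bounds). Among them LUM, which encodes the proteoglycan lumican, was at least 16.7-fold higher. Genes of the BMP response rose in 14 of 15 cases and 0 fell, including BMP4 itself (at least 6.96-fold), MSX2 (at least 9.48-fold) and MSX1 (log2 3.08).

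Pluripotency genes moved the other way with OCT4 shRNA. Of 32 measured members 24 fell and 1 (ZFP42, log2 0.30) rose, with a median of -1.89. IDO1, which encodes a tryptophan-degrading enzyme, was below background on all 4 late arrays and at least 10.2-fold lower, and the DNA methyltransferase gene DNMT3B differed by -3.04. Proliferation genes fell in 24 of 26 cases, with a median of -0.73, and 1 (E2F1, log2 0.27) rose. Cyclin E1 (CCNE1) was lower by a log2 of -1.44 ± 0.14 (SE) and the mitotic checkpoint kinase gene BUB1 by -1.41 ± 0.16 (SE). The largest falls outside these lists were CNMD (log2 -4.49), which encodes chondromodulin, and AASS (log2 -4.46), an enzyme of lysine breakdown. POU5F1 was above background on 3 of 4 late arrays and NANOG on 1. The largest rises included TGFBI (log2 5.69), an extracellular matrix gene, and TRIM55 (at least 35.3-fold), a muscle ubiquitin ligase gene.

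In the camera test these 5 lists passed with the preset correlation and with an estimated one. Adjusted p was 2.99e-12 for trophoblast (0.00253 with an estimated correlation), 6.32e-09 for mesoderm (0.00253), 3.15e-08 for BMP response (0.0243), 3.93e-13 for pluripotency (0.0167) and 3.15e-08 for proliferation (0.0309). A further 5 lists passed with the preset correlation alone. The fibroblast feeder list rose in 9 of 12 members and fell in 1 (adjusted p = 2.26e-04), and its adjusted p = 0.124 with an estimated correlation. It holds COL3A1 (at least 17.2-fold) and COL5A1 (log2 3.56), and 7 of its 12 measured genes stand in the mesoderm list too, so the lists are not independent. HAND1 and ISL1 likewise stand in both the trophoblast and mesoderm lists, and MSX1 and MSX2 in both the mesoderm and BMP response lists. Epithelial to mesenchymal genes rose in 9 of 17 and fell in 1 (adjusted p = 0.00243, and adjusted p = 0.056 with an estimated correlation), among them SNAI2 (log2 4.36, above background on 2 of 4 control arrays), a repressor of epithelial genes. Primitive streak and mesendoderm genes rose in 6 of 15 and 0 fell (adjusted p = 0.0109, and adjusted p = 0.124 with an estimated correlation), led by LEF1 (log2 2.25), a mediator of WNT signals. Its median of 0.44 was 0.14 at bounds. Neuroectoderm genes fell in 6 of 23 and 0 rose (adjusted p = 0.0493, and adjusted p = 0.303 with an estimated correlation), with ZIC2 lower by -3.91 and SOX3 by -2.86. Interferon genes fell in 6 of 20 and 0 rose (adjusted p = 0.0493, and adjusted p = 0.124 with an estimated correlation), with IFITM1 lower by -2.13. With the day as a block, neither the neuroectoderm nor the interferon list passed (adjusted p = 0.0506 for each).

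The other lists did not pass with OCT4 shRNA. Endoderm genes split into 6 higher, such as FLRT3 (log2 4.12, above background on 2 of 4 control arrays), and 4 lower, such as the retinoic acid hydroxylase gene CYP26A1 (log2 -3.55), with adjusted p = 0.917. Genes of the p53 response split into 7 higher and 4 lower (adjusted p = 0.498), with GDF15 lower by -1.55 and CDKN1A higher by 0.71. Hypoxia and glycolysis had 1 higher (NDRG1, log2 2.40) and 5 lower (adjusted p = 0.177), such as ADM (log2 -1.98). Neural crest had 3 higher and 3 lower (adjusted p = 0.917), NODAL and activin response 2 higher and 4 lower (adjusted p = 0.917), and blood and endothelial 1 higher (RUNX1) and 3 lower (adjusted p = 0.257). Median, mean and test differed in sign for neural crest and for NODAL and activin response. Adjusted over the list alone, the counts of all 16 lists were the same as over all genes. Over all 13438 genes, limma called 6467, of which 3199 were higher and 3268 lower, and 1249 of the calls were at least 2-fold (591 higher, 658 lower). Subtracting the difference of days 0 and 1 left 3202 calls, a contrast of slopes over days 3495, and testing probes singly gave 9781. Further probes gave smaller differences for CCNE1 (log2 -0.57) and CYP26A1 (-2.09 and -1.36).

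The comparison of NANOG shRNA with control asked the same question for NANOG. Neuroectoderm genes were higher, with 13 of 23 measured members up and 0 down and a median log2 difference of 0.71 (0.48 at bounds). The homeobox genes LHX5 (log2 2.17 ± 0.22, SE), PAX6 (2.00 ± 0.39, SE) and SIX3 (1.90 ± 0.26, SE) of the developing forebrain and eye led the list, and OTX2 was higher by 1.61. LHX5 and PAX6 were above background on 3 of 4 control arrays and SIX3 on 2. Pluripotency genes fell in 16 of 32 cases with a median of -0.47, and HESX1 (log2 1.80), a homeobox gene of the anterior neural plate and pituitary, rose. GAL, which encodes the neuropeptide galanin, was at 8.05 ± 0.37 (SD, n = 3) against 11.01 ± 0.42 (SD, n = 4), and UTF1 differed by -1.82. The largest rises were the transcriptional cofactor gene LMO1 (log2 3.03 ± 0.25, SE), the ephrin receptor gene EPHA4 (2.85 ± 0.23, SE), the axon guidance gene SLIT2 (2.83 ± 0.24, SE), WLS (2.74), which is needed for WNT secretion, and the activin antagonist FST (2.66). The largest falls were 3 metallothionein genes, MT1G (log2 -3.35), MT1H (-3.20) and MT1X (-3.07), then GAL and the synaptotagmin gene SYT4, at least 5.37-fold lower. Metallothionein paralogs are near-identical and their probes may share signal, so these values are uncertain. A second MT1H probe gave -0.29, and the 4 further probes of WLS gave 0.69, 1.54, 1.89 and 1.99. Without day 5 or day 6 of all arms, or without the NANOG shRNA array of either day, MT1G was no longer called (log2 between -3.28 and -3.20), nor was MT1H without either day of all arms (-3.08 and -3.12).

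The neuroectoderm list passed the camera test (adjusted p = 1.17e-09, and 0.0108 with an estimated correlation). Pluripotency (adjusted p = 5.88e-07) kept no call in that setting (adjusted p = 0.16 with an estimated correlation). BMP response genes rose in 8 of 15 and fell in 1 (adjusted p = 5.86e-05, and adjusted p = 0.16 with an estimated correlation), with MSX1 higher by 1.69, ID3 by 1.56 and ID2 by 1.11, while the decoy receptor gene BAMBI fell (log2 -1.07). Primitive streak and mesendoderm genes rose in 4 of 15 (adjusted p = 0.00762, and adjusted p = 0.178 with an estimated correlation), which were SP5 (log2 2.55, above background on 3 of 4 control arrays), LEF1 (0.88), MESP1 and WNT3A. Its median of 0.24 was 0.00 at bounds, since 10 of the 15 members were below background in a group. The trophoblast list had 2 higher members of 24, TFAP2A (log2 1.12) and DLX5 (0.99), and did not pass (adjusted p = 0.62). Another 4 probes of TFAP2A gave 0.51, 0.20, 0.12 and 0.013, none called. Nor did endoderm (4 higher, 1 lower, adjusted p = 0.241), mesoderm (4 higher, 3 lower, 0.84), neural crest (1 higher, 2 lower, 0.944), NODAL and activin response (3 higher, 1 lower, 0.672) or epithelial to mesenchymal genes (2 higher, 3 lower, 0.816). SOX9 (log2 2.13) was the higher neural crest gene and COL1A1 (log2 -1.59) a lower mesoderm gene. Proliferation had 2 higher, CCND1 (log2 0.86) and TYMS (0.67), and 0 lower of 26 (adjusted p = 0.816). The p53 response had 1 higher and 3 lower (adjusted p = 0.693), interferon 2 higher and 1 lower (0.922), hypoxia and glycolysis 0 higher and 3 lower (0.191), fibroblast feeder 1 higher and 2 lower (0.816), and blood and endothelial 2 higher and 1 lower (0.605), with VWF higher by 2.19 (above background on 3 of 4 control arrays). Median, mean and test differed in sign for proliferation, p53 response and interferon. Adjusted over the list alone, pluripotency had 3 higher and 17 lower, neuroectoderm 15 higher and 1 lower, trophoblast 1 higher, neural crest 1 higher and 3 lower, and hypoxia 4 lower, with the other counts the same.

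Over all genes limma called 2073 with NANOG shRNA, 1056 higher and 1017 lower, of which 134 and 149 were at least 2-fold. Without day 5 of all arms the count was 908 and without day 6 it was 1016, and without only the NANOG shRNA array of these days it was 1330 and 1171. Subtracting days 0 and 1 left 149 calls, the contrast of slopes 364, and array weights gave 4790. Without the NANOG shRNA array of day 6, limma no longer called POU5F1 (log2 -0.90, adjusted p = 0.066), LEF1 (0.46), ID2 (0.90), TFAP2A (0.89) or DLX5 (0.76). Without day 6 of all arms these were at log2 -0.84, 0.41, 0.94, 0.83 and 0.79 in that order, none called. Without day 5 of all arms LEF1 (log2 0.84), ID2 (1.07), TFAP2A (1.01) and DLX5 (0.93) were not called, TFAP2A not without the NANOG shRNA array of day 5 (1.02), and DLX5 not without that array, any late control array, or day 2 or 3 (0.90 to 1.05).

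The comparison of SOX2 shRNA with control gave the fewest calls of the H1 knockdowns, 1109 genes, of which 477 were higher and 632 lower. Genes of the interferon and double-stranded RNA response were higher in 6 of 20 cases and lower in 0. IFIT1, an interferon-induced antiviral gene, was higher by a log2 of 2.30 ± 0.26 (SE, n = 4 and 4), with a second probe at 0.33 that was not called (limma adjusted p = 0.106), ISG15 by 0.62, and IFIT2 was at least 2.52-fold higher. IFIT3 (at least 1.24-fold), IFI27 (at least 1.1-fold) and IFI44 (at least 1.09-fold) had controls below background on all 4 arrays. Probes of the IFIT family may share signal. SOX3, a close relative of SOX2, was higher by a log2 of 2.03 ± 0.21 (SE), the smooth muscle actin gene ACTG2 by 2.08 ± 0.32 (SE) and the WNT receptor gene FZD2 by 1.83 ± 0.14 (SE). SOX21, another SOX family member of neural progenitors, was lower by -4.05 ± 0.40 (SE), with 2 of its 4 late arrays above background. NPTX1 (log2 -3.02) and FEZ1 (-2.84), both neuronal genes, CNMD (-2.78) and TMEM158 (-2.50) completed the largest falls.

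The interferon list passed the camera test with SOX2 shRNA (adjusted p = 1.35e-05, and 0.00248 with an estimated correlation). The 6 members called late had a median difference of 0.58 on days 4 to 7 (0.46 at bounds) and of 0.44 on days 0 and 1 (0.19 at bounds), when none was called. On days 0 and 1 the list of 20, in a test chosen after the result was seen, had adjusted p = 0.00519 (adjusted p = 0.0516 with an estimated correlation), without day 0 adjusted p = 0.00489 (adjusted p = 0.104 with an estimated correlation), and without day 1 adjusted p = 0.798. The list's median of 0.21 was 0.15 at bounds. Mesoderm genes rose in 5 of 22 and fell in 0 (adjusted p = 0.00925, and adjusted p = 0.273 with an estimated correlation), including PDGFRB (log2 1.22) and ISL1 (1.35, above background on 3 of 4 arrays against 1 of 4). Its median of 0.15 was 0.00 at bounds. Pluripotency genes fell in 6 of 32, SOX2 and IDO1 (log2 -1.34) among them, and 0 rose (adjusted p = 0.0113, and adjusted p = 0.626 with an estimated correlation). Genes of the p53 response rose in 4 of 17 and fell in 0 (adjusted p = 0.0127, and adjusted p = 0.626 with an estimated correlation), with the cell cycle inhibitor gene CDKN1A higher by 1.02. The fibroblast feeder list had 2 higher, PDGFRB and COL1A2 (log2 1.00), of 12 (adjusted p = 0.0395, and adjusted p = 0.626 with an estimated correlation). Of the lists that did not pass, neuroectoderm had 3 higher and 2 lower (adjusted p = 0.633), neural crest 3 higher and 1 lower (0.535) with SOX9 at 1.39 and SOX8 at -1.32, trophoblast 2 higher (0.233), endoderm 1 lower (KIT, log2 -0.91, list p 0.709) and primitive streak 0 (0.535). BMP response had 2 higher (adjusted p = 0.282), BAMBI (log2 1.06) and ID3 (0.70), epithelial to mesenchymal 2 higher (0.233), proliferation 2 higher and 1 lower (0.633), and blood and endothelial 1 higher (0.699). NODAL and activin response (adjusted p = 0.282) and hypoxia and glycolysis (0.743) had 0 called. Adjusted over the list alone, interferon had 7 higher, mesoderm 6 higher, pluripotency 7 lower, p53 response 6 higher and 1 lower, and BMP response 3 higher and 1 lower, with the other counts the same.

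At least 2-fold were 99 of the SOX2 shRNA calls, 33 higher and 66 lower, and 91.9% of these had the same sign on days 0 and 1. After subtraction of days 0 and 1, 4 genes were called, FZD2 higher and FEZ1, CNTN1 and IL17RB lower, and the contrast of slopes called 3. Without day 5 of all arms the count was 490 and without day 6 it was 736. Days 5 to 7 alone gave 684, a fit of these 2 arms alone 1885 and array weights 2293. ISL1 lost its call without day 6 or 7 of all arms (log2 1.19 and 0.94) or the SOX2 shRNA array of day 7 (0.85), and CDKN1A without day 5 (1.02) or the control array of day 7 (0.84). ISG15 (log2 0.45 to 0.70) and COL1A2 (0.94 to 1.08) lost theirs without any 1 of days 2 to 6, of the SOX2 shRNA arrays of days 4, 5 and 7, or of the control arrays of days 4 and 6, and COL1A2 also without that of day 5. Further probes of EDNRB, which was called higher (log2 0.76), gave 0.25 and -0.18, those of NPTX1 -1.01 and -1.08 and those of FEZ1 -2.53, -0.92 and -0.39.

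**Figure D3:**
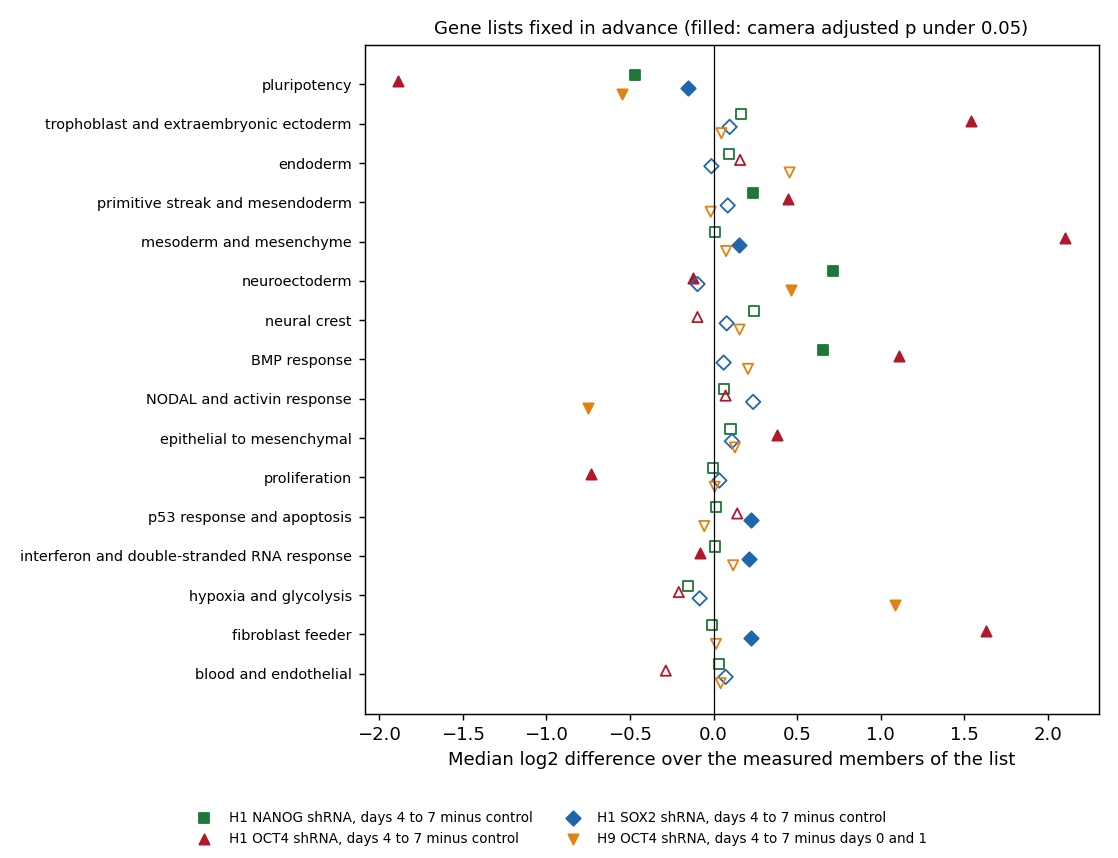
Median log2 difference (x axis) over the measured members of each of 16 gene lists (y axis), for the 3 H1 knockdown arms against control (NANOG shRNA on days 4 to 6 only) and for H9 cells with OCT4 shRNA over time, with filled symbols where the camera adjusted p with the preset correlation was under 0.05. The mesoderm median stood at 2.10 with OCT4 shRNA, and the neuroectoderm median at 0.71 with NANOG shRNA.

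Direct tests between the H1 knockdowns on days 4 to 7 asked where they differ. The NANOG shRNA arm held days 4 to 6 only, so its comparisons are unbalanced in days. Between NANOG and OCT4 shRNA limma called 5802 genes, 2940 higher and 2862 lower with NANOG shRNA. CYP26A1 (log2 4.87), POU5F1 (4.73) and ZIC2 (4.61) were the furthest higher, with further probes of CYP26A1 at 2.46 or more and of POU5F1, near background, at -0.044, and HAND1 (-7.34, above background on 2 of 3 NANOG shRNA arrays), GABRP (at least 82.5-fold lower) and TRIM55 (at least 35.3-fold lower) the furthest lower. Neuroectoderm genes were higher with NANOG than with OCT4 shRNA in 15 of 23 cases and lower in 0 (adjusted p = 2.58e-08, and 0.0105 with an estimated correlation). Proliferation genes were higher in 23 of 26 (adjusted p = 2.16e-09, and 0.0221 with an estimated correlation), and trophoblast genes lower in 19 of 24 and higher in 1 (3.6e-12, and 0.00228 with an estimated correlation). Mesoderm genes were lower in 17 of 22 and higher in 2 (1.27e-09, and 0.00228 with an estimated correlation), and 5 further lists passed with the preset correlation alone (adjusted p between 0.0585 and 0.135 with an estimated correlation). Between NANOG and SOX2 shRNA 2436 genes were called, 1285 higher and 1151 lower with NANOG shRNA. SOX21 (log2 5.01), the imprinted gene DLK1 (4.25) and PAMR1 (4.01) were the furthest higher, and GAL (-3.44), SYT4 (at least 7.6-fold lower) and the noncoding RNA gene UCA1 (-2.94) the furthest lower. Neuroectoderm was higher with NANOG shRNA in 14 of 23 and lower in 1 (adjusted p = 2.81e-08, and 0.0194 with an estimated correlation), and interferon genes lower in 6 of 20 (0.00157, and 0.0194 with an estimated correlation), and 4 further lists passed with the preset correlation alone (adjusted p between 0.309 and 0.437 with an estimated correlation), of which fibroblast feeder was lost with the day as a block (adjusted p = 0.0682). Without day 5 or day 6 of all arms this comparison called 1325 and 1427 genes, and with array weights 4937. Between OCT4 and SOX2 shRNA 6349 genes were called, 3190 higher and 3159 lower with OCT4 shRNA. HAND1 (log2 6.44, above background on 2 of 4 SOX2 shRNA arrays), TRIM55 (at least 35.3-fold) and TGFBI (5.58) were the furthest higher, and POU5F1 (-5.85, and -0.34 by its second probe), SOX3 (-4.89) and ACTG2 (-4.49) the furthest lower. Interferon genes were lower with OCT4 than with SOX2 shRNA in 13 of 20 (adjusted p = 1.18e-05, and 0.00268 with an estimated correlation). Trophoblast genes were higher in 19 of 24, mesoderm genes in 15 of 22 and BMP response genes in 13 of 15, and pluripotency genes were lower in 23 of 32 and proliferation genes in 23 of 26 (adjusted p between 0.00268 and 0.0212 with an estimated correlation). The remaining 3 lists that passed with the preset correlation had adjusted p between 0.149 and 0.32 with an estimated correlation.

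Genes called in the same direction in more than 1 knockdown were counted next. NANOG and OCT4 shRNA shared 456 higher and 661 lower genes, with 274 opposite, where independent lists would share 251, 247 and 499. NANOG and SOX2 shRNA shared 111 higher and 195 lower, with 89 opposite (independent lists 37.5, 47.8 and 85.8). OCT4 and SOX2 shRNA shared 203 higher and 418 lower, with 152 opposite (independent lists 114, 154 and 266). All 3 knockdowns shared 60 higher and 161 lower genes (independent lists 8.92 and 11.6). With a difference of at least 2-fold in all 3, 6 genes were higher and 19 lower (independent lists 0.0145 and 0.0358). The knockdowns share their control arrays. In 20 simulated sets of unchanged arms, every array, controls included, was drawn as independent noise about the control means. Shared calls numbered 0 in each direction. Unchanged arms give almost no calls, so this count was fixed in advance. It cannot show how many shared calls the common controls produce. The sets also lack the same-day correlation of the arrays. Differences across genes still correlated in them. The covariance across genes was 0.0844 for NANOG and OCT4 shRNA against a simulated 0.00994, 0.0218 for NANOG and SOX2 shRNA against 0.0101, and 0.0515 for OCT4 and SOX2 shRNA against 0.00995. Pearson's r across genes, which are not independent replicates, was 0.356, 0.234 and 0.293 (simulated 0.461, 0.467 and 0.498), and with the control arrays split between the arms it was 0.312, 0.142 and 0.235.

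Change over time in the H1 control arm was measured as the background for H9. Between days 0 and 1 and days 4 to 7, 71 genes changed, 21 rising and 50 falling. COXFA4L2, a hypoxia-inducible mitochondrial gene, was at least 4.96-fold higher, UPK1A rose by a log2 of 1.18 and ZCCHC12 by 0.92 (above background on 1 of 2 early arrays). The ERK phosphatase gene DUSP6 (log2 -1.84), the amino acid transporter gene SLC7A5 (-1.54) and DACT1 (-1.44) fell most among the called genes. The NODAL and activin list fell (median -0.63, 0 higher and 2 lower of 12, adjusted p = 0.00106) and the hypoxia and glycolysis list rose (median 0.23, 0 called of 15, adjusted p = 0.00106), each with adjusted p = 0.344 with an estimated correlation. Adjusted over the list alone, NODAL and activin had 1 higher and 5 lower, hypoxia 2 higher, endoderm 3 higher and 1 lower, interferon 2 higher, pluripotency 3 lower, BMP response 2 lower, and proliferation and blood and endothelial 1 lower each, with the other counts the same. The other 14 lists did not pass (adjusted p between 0.0786 and 0.888), and median, mean and test differed in sign for pluripotency, primitive streak and fibroblast feeder. Without day 0, 1, 5, 6 or 7 of all arms the count of 71 became 11, 9, 11, 16 and 37, and without day 4 it was 171. Without only the control array of day 5, 6 or 7 it was 41, 38 and 31, and with the day as a block 185. That block called 4 lists in place of 2, adding pluripotency (adjusted p = 0.024), proliferation (0.0166) and p53 response (0.0464) and losing NODAL and activin (0.281), and it ended the call of DACT1 (log2 -1.11, adjusted p = 0.105), of which further probes gave -1.44 and -0.067. Without day 0 of all arms DUSP6 (log2 -1.62), SLC7A5 (-1.49), DACT1 (-1.61), UPK1A (1.06) and ZCCHC12 (0.55) lost their calls. Without day 1 or day 6 DUSP6 (log2 -2.05 and -1.60), UPK1A (1.30 and 1.17), ZCCHC12 (1.29 and 0.98) and DACT1 (-1.28 and -1.36) lost theirs, and without day 5 the last 3 did (1.17, 0.94 and -1.51). ZCCHC12 was also lost without day 7 or any late control array (log2 0.83 to 0.98), and DACT1 without day 7 or the control array of day 5, 6 or 7 (-1.51 to -1.36).

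In H9 cells with OCT4 shRNA the change over time was asked in the absence of a control arm. POU5F1 fell by a log2 of 2.37 (9.33 ± 0.66, SD, n = 4, on days 4 to 7, and 11.69 ± 0.22, SD, n = 2, on days 0 and 1), and NANOG changed by -2.23 and SOX2 by 1.29. A second NANOG probe was near background in H9 cells and gave -0.53, a second SOX2 probe gave 0.66, and the second POU5F1 probe gave -0.61. The 2 NANOG probes were at 10.65 and 6.69 in H9 cells on day 0, but at 8.91 and 8.63 in H1 control cells. The cause of this disagreement in H9 was not tested, and the size of the NANOG change there is uncertain. Pluripotency genes fell in 17 of 32 cases and rose in 3 (SOX2, HESX1 and LIN28B), with a median of -0.55. LEFTY1, a NODAL antagonist and target, changed by -3.37 ± 0.61 (SE) and L1TD1 by -2.07. In H1 control cells LEFTY1 differed by -1.97 between the same windows and did not pass (adjusted p = 0.134). Hypoxia and glycolysis genes rose in 11 of 15 and 0 fell, with a median of 1.08, among them NDRG1 (log2 2.23), ANKRD37 (2.04) and the mitophagy gene BNIP3 (1.85). Neuroectoderm genes rose in 9 of 23 and 1 (EMX2) fell, with SIX6 (log2 2.81), the microtubule gene MAP2 (2.68) and SIX3 (2.42) ahead. MAP2, SIX3 and ANKRD37 were above background on 1 of 2 early arrays. NODAL and activin genes fell in 7 of 12 and 1 (FST, log2 1.91) rose. The NODAL and pluripotency lists share NODAL, LEFTY1, LEFTY2, TDGF1 and GDF3, so their falls are not independent. The largest rises were DLK1 (log2 4.24 ± 0.53, SE), SOX21 (3.87 ± 0.49, SE), COXFA4L2 (at least 8.75-fold), the glucose-responsive gene TXNIP (3.22) and the WNT antagonist FRZB (3.20). CHGA (log2 -3.22), the RNA polymerase III subunit gene POLR3G (-2.87) and THY1 (-2.58) were among the largest falls.

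For H9 cells the camera test gave adjusted p = 1.07e-08 for hypoxia and glycolysis (0.0336 with an estimated correlation). It gave 5.69e-05 for pluripotency, 0.00198 for neuroectoderm and 0.00198 for NODAL and activin, each with adjusted p = 0.208 with an estimated correlation. The NODAL median of -0.75 was -0.40 at bounds. Adjusted over the list alone, pluripotency had 3 higher and 18 lower, hypoxia 12 higher, NODAL and activin 1 higher and 8 lower, primitive streak 2 and 7, neural crest 2 and 2, p53 response 5 and 3 and epithelial to mesenchymal 2 and 1, with the other counts the same. The hypoxia and NODAL lists had the same sign in the H1 control arm. Trophoblast had 2 higher and 1 lower of 24 (adjusted p = 0.745), endoderm 7 higher and 3 lower of 17 (0.122) with CYP26A1 at 2.44, primitive streak 2 higher and 5 lower (0.745), and mesoderm 1 higher (MEIS2) and 1 lower (0.84). Neural crest had 2 higher and 1 lower (adjusted p = 0.745), BMP response 5 higher and 2 lower (0.717) with ID2 at 2.84, epithelial to mesenchymal 3 higher and 1 lower (0.745), and proliferation 2 higher and 4 lower (0.745) with RRM2 at -1.71. The p53 response had 4 higher and 3 lower (adjusted p = 0.851), interferon 5 higher and 1 lower (0.556), fibroblast feeder 1 higher and 1 lower (0.851), and blood and endothelial 1 higher (0.745). Median, mean and test differed in sign for proliferation and fibroblast feeder. Over all genes limma called 3636, of which 1870 rose and 1766 fell. Without day 0 of all arms 1970 were called and without day 1 2271, a fit of the H9 arm alone called 2383, and probes tested singly gave 5534. Without day 1 of all arms SOX2 was no longer called (log2 1.2, adjusted p = 0.0679), and with the day as a block the endoderm list passed (adjusted p = 0.0424). Further probes of ZMAT3, which fell (log2 -1.26), gave 0.14 and -0.59. Those of MAP2 gave 2.76, 0.77 and 0.62, those of CYP26A1 1.59 and 1.14, those of POLR3G -2.12 and -0.17, and that of MEIS2 0.12 against 2.24.

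**Figure D4:**
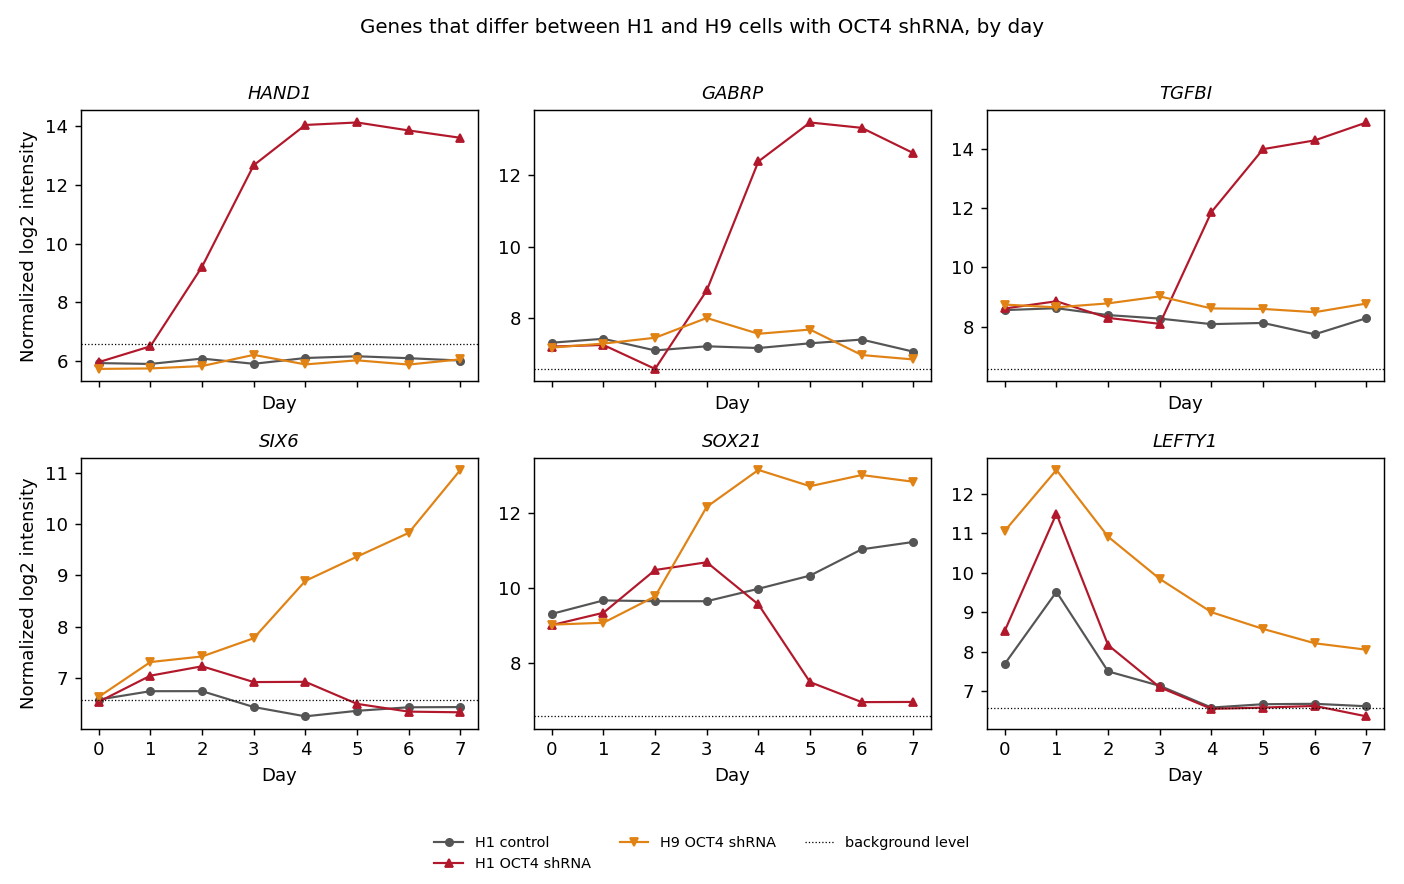
Normalized log2 intensity (y axis) by day (x axis) of 6 genes in H1 control cells and in H1 and H9 cells with OCT4 shRNA, 1 array per point. HAND1, GABRP and TGFBI went up in the H1 OCT4 shRNA arm, SIX6 and SOX21 in the H9 arm, and LEFTY1 went down in all 3 arms after day 1.

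The change over time with OCT4 shRNA was then compared between the lines by a test of the difference. H1 cells with OCT4 shRNA had 5655 called changes, among them the growth factor binding protein gene IGFBP3 (log2 5.87), CAMKV (-3.73) and the pluripotency list member VSNL1 (-3.61, above background on 3 of 4 late arrays). The change differed between H9 and H1 for 3821 genes, 1891 higher and 1930 lower in H9. Trophoblast genes changed less upward in H9 than in H1 in 17 of 24 cases (1 more upward), with a median difference of -1.50, or -1.49 with values below background at that level (adjusted p = 8.27e-11, and 0.00431 with an estimated correlation). HAND1 and TRIM55 were below background on all H9 arrays of both windows, and in H1 they rose at least 162-fold and at least 35.3-fold from below background. GABRP differed by -5.68. Mesoderm genes differed downward in 12 of 22 and upward in 1 (adjusted p = 3.08e-08, and 0.00431 with an estimated correlation). SOX21 (5.30 ± 0.70, SE), DLK1 (4.57) and CYP26A1 (4.55, and 2.48 and 1.67 by further probes) differed upward, and SOX2 itself by 4.26. Neuroectoderm genes differed upward in 12 of 23 and downward in 0 (adjusted p = 1.76e-05, and adjusted p = 0.0637 with an estimated correlation). A further 7 lists passed with the preset correlation alone, upward for pluripotency, proliferation, interferon, hypoxia, and blood and endothelial, and downward for BMP response and fibroblast feeder, with adjusted p between 0.065 and 0.151 with an estimated correlation. Without day 0 of all arms the difference was called for 1792 genes and without day 1 for 2464. A fit of these 2 arms alone called 2428, and probes tested singly gave 5826.

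**Figure D5:**
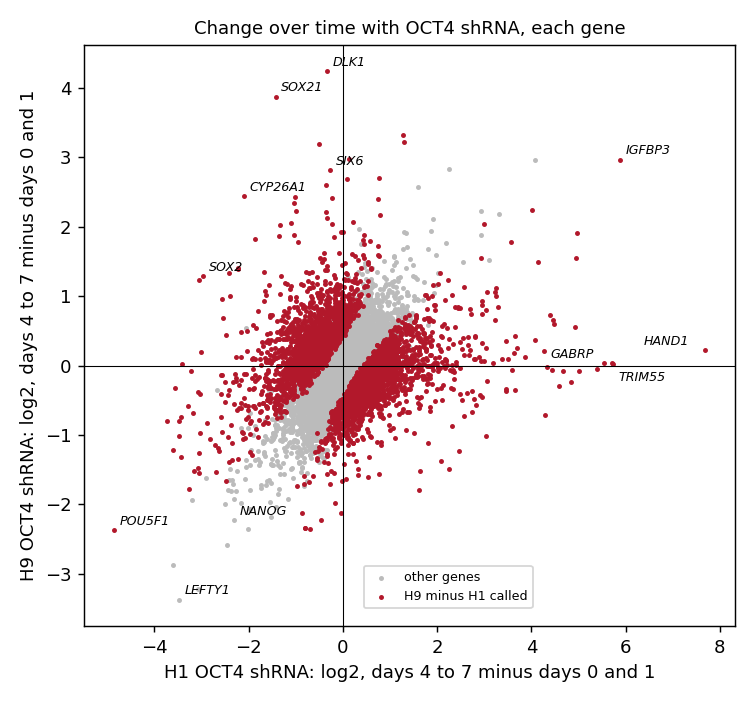
Change over time with OCT4 shRNA (log2, days 4 to 7 minus days 0 and 1) in H1 cells (x axis) and H9 cells (y axis), 1 point per gene of 13438, with the 3821 genes whose change differed between the lines in red. HAND1 lies far to the right with a small H9 change, and SOX21 and DLK1 lie at the top.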

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

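The tests of the H9 and H1 difference were set before its result was seen, and the comparison of the left-out column was chosen after the data were seen.

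The change over time with OCT4 shRNA differed between H9 and H1 by a test of the difference for 3821 genes. SOX21 (5.30), DLK1 (4.57) and CYP26A1 (4.55) changed further upward in H9, and GABRP (-5.68) further upward in H1, as were HAND1 and TRIM55, whose fitted differences (-7.46 and -5.72) rest on H9 values below background and measure no fold. The repair of the H9 values is argued against as the source of this difference. Of genes whose H9 values were not moved, 30.1% were called, against 28.4% of all genes. Of 1891 genes called in both changes, 22.3% went opposite ways (265 higher in H9 and lower in H1, 157 the reverse). That share is just past the bound of 20% set in advance against a weaker knockdown alone. The bound takes a weaker knockdown to keep nearly every sign, and drift in H9 could turn signs too, so a weaker knockdown stays open. POU5F1 was at 8.54 on day 7 in H9 cells and at 6.46 in H1 cells with OCT4 shRNA. Drift of cultures over time stays open, because the H9 line had no control arm and its change correlated with the H1 control change. That correlation was 0.450 over the 3821 called genes and 0.454 over all genes. For the H1 OCT4 shRNA change the correlation with the H1 control change was 0.102 and 0.218. A difference between the lines in their response to OCT4 loss could not be separated from drift.

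The left-out NANOG shRNA column of day 7 holds a signal above that between control arrays. Its scale is unknown, so its values were ranked, given the distribution of the other arrays, and compared with day 7 of control. Its difference correlated at 0.806 with that of days 4 to 6 over 2073 called genes, with 85.0% of signs the same and NANOG at -2.63. The highest such correlation for differences of 2 late control arrays was 0.333 over 12 ordered pairs.

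A late array far from the other 3 of its arm was found in 16 of 267 groups of named calls (5.99%), and chance flags about 1 in 20 groups. Over all named genes and arms, the scope first run and then narrowed to the arms each comparison uses, it was 24 of 556 (4.32%). Days are ordered, so a far day can be the end of a trend. The values are the gap to the nearest other array over the range of the 4. In H1 control these were WLS on day 7 (0.855), SYT4 on day 4 (0.8295), LEF1 (0.893), IFITM1 (0.884), VWF (0.850) and BAMBI (0.935) on day 6, and TRIM22 on day 7 (0.874). In H1 cells with OCT4 shRNA they were AASS (0.943), LUM (0.878) and SPATA18 (0.914) on day 4 and BMP4 on day 5 (0.877). In H1 cells with SOX2 shRNA they were CLDN6 on day 4 (0.881), E2F1 on day 5 (0.936) and TGFBI on day 7 (0.848), and in H9 cells CHGA (0.838) and PMAIP1 (0.886) on day 4.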

How the results depend on the processing

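Of the settings here, the normexp offset of 16, days 4 to 6 alone, H9 genes in rows not moved and centring of each array were chosen after seeing the data. A chip block was not run, since no header gives the chip, and neither was scaling to a common median, since the deposited medians are nearly equal. The neqc and detection p settings were replaced by normexp and filters on the background level, since those columns match no label. Over 225 pairs of a named gene and a comparison, refitted under each setting that applies, the side of the threshold and the direction held in 3505 refits, a call was lost in 220 and gained in 2. With a day or array left out they held in 3058 refits and a call was lost in 226, and with another probe they held in 73 and a call was lost in 22. Sign changes of values called in neither setting numbered 5, 8 and 3. Another probe turned the sign of EDNRB with SOX2 shRNA (-0.18), ZMAT3 in H9 (0.14) and POU5F1 between NANOG and OCT4 shRNA (-0.044). Signal over background limits the dim genes, for which folds are bounds. Single probes are counted in place of genes, and left-out arrays leave fewer samples; for the other changes below the cause was not tested.

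Subtracting the early difference gave 149 calls with NANOG shRNA, 3202 with OCT4 shRNA and 4 with SOX2 shRNA, and the contrast of linear slopes gave 364, 3495 and 3. Array quality weights gave 4790 with NANOG shRNA, 2293 with SOX2 shRNA, 4937 between NANOG and SOX2 shRNA, 378 in the H1 control change and 8 in the early SOX2 shRNA difference. All probes singly gave 9781 with OCT4 shRNA, 8748 between NANOG and OCT4 shRNA, 9805 between OCT4 and SOX2 shRNA, 5534 in the H9 change, 8559 in the H1 OCT4 shRNA change, 5826 between H9 and H1 and 0 in the early NANOG shRNA difference. Only the arms compared gave 1885 with SOX2 shRNA, 390 in the H1 control change, 2383 in the H9 change, 2428 between H9 and H1, and 2, 1 and 7 in the early NANOG, OCT4 and SOX2 shRNA differences. The late window of days 5 to 7 gave 684 with SOX2 shRNA. Genes whose H9 rows were not moved, which are fewer, gave 1379 in the H9 change and 1513 between H9 and H1. A normexp offset of 16 gave 38 in the H1 control change and 0 in the early NANOG shRNA difference, as did no background correction (0) and cyclic loess (0). The early OCT4 shRNA difference gave 1 with no background correction and 1 with deposited intensities on the log2 scale.

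With the day as a replicate block, the pairing given by the labels, the H1 control change had 185 calls and 4 called lists, and the early NANOG shRNA difference 2 calls. The block ended the calls of DACT1 in the control change (-1.11) and of TFAP2C (0.93), EOMES (-0.64), NGFR (0.33) and IFITM1 (0.56) in the H9 change. It ended the list calls of neuroectoderm and interferon with OCT4 shRNA, fibroblast feeder between NANOG and SOX2 shRNA, NODAL and activin in the control change and neuroectoderm in the H1 OCT4 shRNA change, and added pluripotency, proliferation and p53 response in the control change and endoderm in the H9 change. It changed no other call of a named gene or list and moved no other count of calls by over 1.5 times.

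Camera with an estimated correlation called 1 list with NANOG shRNA, 5 with OCT4 shRNA, 1 with SOX2 shRNA, 4 between NANOG and OCT4 shRNA, 2 between NANOG and SOX2 shRNA, 0 in the H1 control change, 1 in the H9 change, 4 in the H1 OCT4 shRNA change and 2 between H9 and H1. Fry called 2 with SOX2 shRNA and 0 in the H1 control change. Shared calls at a 2-fold threshold numbered 44 higher and 103 lower for NANOG and OCT4 shRNA, 8 and 19 for NANOG and SOX2 shRNA, and 13 and 48 for OCT4 and SOX2 shRNA.

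Leaving out each day or array in turn gave counts from 908 to 1989 with NANOG shRNA, 5317 to 6615 with OCT4 shRNA, 490 to 1077 with SOX2 shRNA, 4369 to 6045 between NANOG and OCT4 shRNA, 1325 to 2362 between NANOG and SOX2 shRNA and 5112 to 6495 between OCT4 and SOX2 shRNA. For the changes over time they ran from 9 to 171 in H1 control, 1970 to 3923 in H9, 3955 to 5904 in H1 OCT4 shRNA and 1792 to 4271 between H9 and H1. For the early differences they ran from 0 to 1 with NANOG shRNA, 0 to 2 with OCT4 shRNA and 0 to 2 with SOX2 shRNA.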

Other observations

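The tests of the interferon genes and of the early levels were chosen after the results were seen, and the splits of arrays were set before.

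Genes with at least a 2-fold call in all 3 H1 knockdowns were named after their values were seen. FZD2, which encodes a WNT receptor, and WLS, needed for WNT secretion, were among the 6 genes higher in all 3, with log2 differences of 2.59 and 2.74 with NANOG shRNA, 1.58 and 4.40 with OCT4 shRNA, and 1.83 and 1.41 with SOX2 shRNA. SLIT2 was higher by 2.83, 2.43 and 1.26 in the same order, SOX9 by 2.13, 1.52 and 1.39, and IGDCC3 by 1.71, 2.69 and 1.30. Of the 19 lower genes, the immediate early gene EGR1 differed by -1.29, -2.09 and -1.72, the deacetylase gene SIRT1 by -1.46, -1.54 and -1.38, PRODH, which encodes proline dehydrogenase, by -1.28, -2.46 and -1.91, and CNMD by -1.84, -4.49 and -2.78. The alpha globin genes HBA1 and HBA2 were lower too, and their values are uncertain because the copies are near-identical. The knockdowns share their control arrays, so part of the overlap can come from those.

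Part of the late differences stood on days 0 and 1. Of all late calls, 74.5% had the same sign early with SOX2 shRNA, 69.8% with NANOG shRNA and 57.8% with OCT4 shRNA, and of the 2-fold calls 91.9%, 78.4% and 62.9%. Over the 2-fold calls the early difference per unit of late difference was 0.325, 0.150 and 0.0444 in that order. These shares use the early and late arrays of 1 arm and control each, and no test compared the arms.

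Interferon genes were higher in the SOX2 shRNA arm, and as a list higher there than with NANOG shRNA (adjusted p = 0.00157) or OCT4 shRNA (adjusted p = 1.18e-05). These tests over all 20 members argue against an equal response to any shRNA virus, though both reuse the SOX2 shRNA arrays that flagged the list. The test against OCT4 shRNA also holds the fall of interferon genes below control in that arm. The 6 members called with SOX2 shRNA, chosen for that call, had a median late difference of 0.0918 with NANOG shRNA and 0.0508 with OCT4 shRNA. An offset of the arm from the start stays open, because their median early difference was 0.44 against 0.58 late, but 0.19 against 0.46 with dim members at their bounds. An effect of this shRNA rather than the loss of SOX2 cannot be told apart from the loss itself, as the design holds 1 SOX2 shRNA arm.

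NANOG and SOX2 were already lower on days 0 and 1 in their own arms, by -1.47 (adjusted p = 0.0448) and -1.97 (adjusted p = 0.107, not called). An offset of many genes as large as that of the targeted gene is argued against, since at most 1 other gene lay as far below control in either arm. A smaller offset stays open. Of the 2-fold late calls, 91.9% with SOX2 shRNA and 78.4% with NANOG shRNA had the same sign on days 0 and 1. A late array in place of the day 0 array is argued against too, since the day 0 array had at most 2.30% as many genes 2-fold apart as the day 4 array. What day 0 means relative to transduction is not given in the labels and stays open.

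Every late comparison of the H1 arms was set against the other splits of its arrays into groups of the same sizes, 35 in each. In each of the 6 comparisons 1 of the 35 splits, the real one, gave as many calls, which excludes chance only as a random assignment of these arrays and says nothing of the spread between cultures. The real and highest other counts were 2073 and 1002 for NANOG shRNA, 6467 and 2971 for OCT4 shRNA, and 1109 and 70 for SOX2 shRNA. They were 5802 and 5089 between NANOG and OCT4 shRNA, 2436 and 1071 between NANOG and SOX2 shRNA, and 6349 and 2525 between OCT4 and SOX2 shRNA. The 8 splits that part every same-day pair, the real one included, are too few for a share under 0.05 and had highest other counts of 676, 2085, 0, 3321, 1071 and 1802 in that order, and the remaining splits put both arrays of at least 1 day on the same side.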
